A study of Mus musculus with 6 samples.

How the data were processed

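Bulk RNA from the nucleus accumbens, a ventral striatal brain region, of adult C57BL6 male mice aged 8 weeks was profiled in 6 libraries. Per the labels, 3 samples had received a herpes simplex virus vector carrying the long noncoding RNA Gas5 together with EGFP, and 3 had received the same kind of vector with EGFP alone, called GFP here. Libraries were made from total RNA after ribosomal RNA depletion with a strand-marking kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, Trim Galore 0.4.4, STAR 2.7.0, featureCounts 1.5.0-p3, edgeR 3.20.9 and the mouse genome build GRCm38. The annotation release, the strand setting and the treatment of reads that fall on several genes are not given in the sources used here.

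The deposited values are raw counts per gene, with no normalization, in whole numbers per the file headers and values. Each table listed 54658 genes. The length column equals the whole span of a gene, so intronic reads were counted, and genes spanning over 100 kb held between 51.0% and 53.6% of the counts of a library. Gene models were matched to GENCODE release M21 of the same build by coordinates, which gave a match for 99.9% of the listed genes. A spreadsheet-style conversion had turned 26 gene symbols into dates or numbers, and 25 of them were restored from their coordinates. Overlaps were checked on protein-coding genes longer than 500 bases. None of the 776 genes lying within a gene on the opposite strand had a count, nor did any of the 405 lying within a gene on the same strand, whereas 17956 of 20521 genes that were not nested had counts. Reads in any overlap of annotated genes are therefore absent from these counts, and strand was not used to assign them. A gene that shares part of its span is measured on the remainder only, and antisense transcription outside annotated genes cannot be told apart from the gene itself.

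The total count per library ranged from 32359052 to 56081575, and between 23319 and 24547 genes had at least 1 count. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 5.13 and 25.2, so they are not repeat sequencing of 1 library, which does not show that they come from separate animals. Each library was counted as a replicate because the labels list it as a separate sample. The labels describe a virus injection for each sample but do not say whether a sample is 1 mouse or a pool, so p-values measure the spread between these samples.

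Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by the default expression filter of edgeR, which left 17563, and libraries were scaled by TMM. Gas5 minus GFP was tested in all 6 libraries with the quasi-likelihood F-test of edgeR, 2-sided, and p-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Standard errors given for edgeR are the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 8.28%. CPM values are scaled by TMM, and logarithms of CPM use a pseudocount of 0.5. For Gas5 an exact permutation test on log2 CPM was added.

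A total of 35 gene lists, 16 of them markers of cell types, were fixed before the data were examined, and 34 had the required 3 or more tested members. The list of snoRNAs encoded in Gas5 had 0 tested members. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and with fry beside it. The name pattern for ribosomal proteins also takes Rps6kl1, which encodes a kinase-like protein, and the histone pattern also takes histone variants. Named genes were chosen by a rule set in advance. They are Gas5, the 10 genes in each direction with the largest log2 fold change among those past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, and the 2 tested members of smallest p in each list. Symbols that are placeholders were only counted. The rule also takes 1 gene that is not reported here, and no other was named in its place. Other list members named in the text were chosen after their values were seen.

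Alternatives set in advance were RLE and upper quartile scaling, no expression filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the exact test of edgeR, robust dispersion, the replicate letter as a block, other thresholds and leaving out each library. Alternatives added after seeing the data were a cortical marker score as a covariate (also in DESeq2 and limma-voom, and with an estimated correlation in camera), removal of the trend with gene span, and leaving out genes that overlap others. The score is the mean log2 CPM of the fixed list of cortical excitatory neuron markers. The fits were tested on simulated data for this comparison, with counts of 17563 genes, of which 17386 passed the filter. In these data 200 genes were changed, and recovery was counted over them. A test list of 20 other genes was also changed, by 0.5 on the log2 scale. Calls among those 20 stayed in the total of calls but were not counted as false. No effect of the cortical marker score was put into the simulated counts. The quasi-likelihood test recovered 65% of genes changed by 0.5 on the log2 scale and 96% of those changed by 1, and 6.99% of its calls were false. With the cortical score as a covariate, 0% and 13% were recovered and 40.9% of the calls were false, against 3% and 42% with 37.8% false in DESeq2 and 0% and 8% with 52.9% false in limma-voom. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.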

Results

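The series asks about the long noncoding RNA Gas5 in the action of cocaine, and the comparison available here is between nucleus accumbens tissue given Gas5 by viral vector and tissue given EGFP alone. Each group had 3 libraries, lettered A, B and C. Total counts were 41195696, 42524874 and 38605056 in the Gas5 libraries and 56081575, 39766777 and 32359052 in the GFP libraries. Mitochondrial genes held between 2.05% and 2.52% of the counts. The first principal component of the 2000 most variable genes carried 70.9% of their variance and separated the groups, with the Gas5 libraries at -24.7, -10.6 and -9.16 and the GFP libraries at 8.13, 18.5 and 17.8. The component also ran broadly along the cortical marker score, at 1.997, 2.67 and 2.86 in the Gas5 libraries and 3.85, 4.34 and 4.39 in the GFP libraries. Its variance therefore cannot be credited to the vector alone.

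Gas5, the gene delivered by the vector, was higher in the Gas5 libraries by 1.30-fold. It stood at 23.2 CPM ± 0.545 (SD, n = 3) in the Gas5 group and at 17.8 CPM ± 1.15 (SD, n = 3) in the GFP group. The log2 fold change was 0.38 with a standard error of 0.0633 and an edgeR adjusted p of 0.0163. All 3 Gas5 libraries lay above all 3 GFP libraries, and the exact permutation test gave p = 0.1, 2-sided, the smallest that 3 against 3 libraries allow. Raw Gas5 counts were 973, 995 and 916 against 1035, 635 and 580. Gas5 ranked 271 among all tested genes by p. The gene lies on chromosome 1 of GRCm38 from 161034422 to 161038539 on the plus strand, and 3760 of its 4118 bases are annotated as exon. It shares 26.6% of this span with 10 other listed genes, among them Zbtb37 on the opposite strand and small nucleolar RNA genes, so the reads of those parts are not counted. The call was lost without GFP B (log2 fold change 0.33, adjusted p 0.0727), without GFP C (0.40, adjusted p 0.0677) and with the cortical marker score in the model (0.38, standard error 0.187, adjusted p 1.0).

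**Figure D1:**
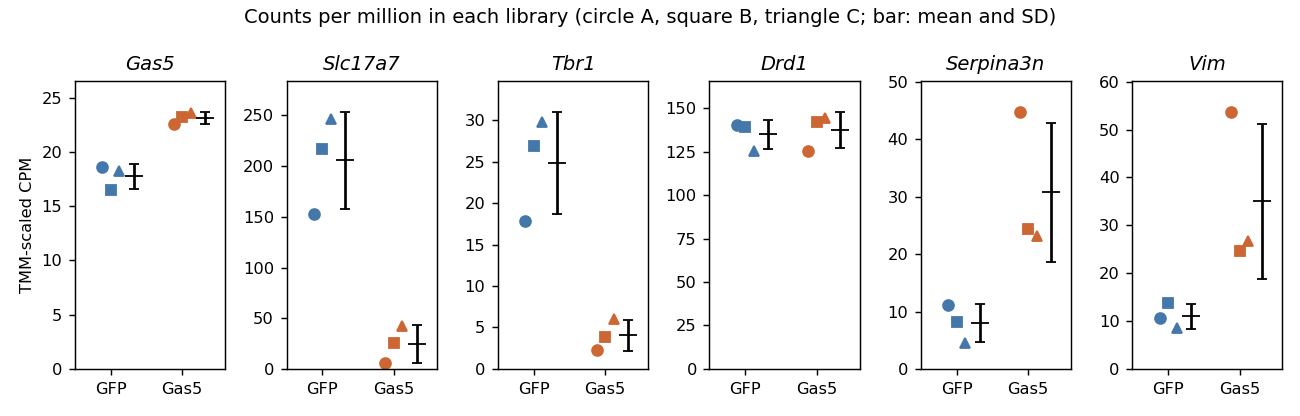
TMM-scaled CPM of 6 genes in each library, with GFP libraries in blue and Gas5 libraries in orange, and the mean and SD of each group as bars beside the points (n = 3). Slc17a7 averaged 206 CPM in the GFP group and 24.5 CPM in the Gas5 group, and the Gas5 transcript 17.8 and 23.2 CPM.

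Other genes near Gas5 and other hosts of small nucleolar RNAs did not pass the test. With edgeR, 0 of the 7 tested chromosomal neighbours were called, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2, limma-voom or the exact test, and their median log2 fold change was -0.01 (0.02 under upper quartile scaling), with log2 fold changes of -0.06 for Rc3h1 and -0.19 for Serpinc1. Of 14 snoRNA host genes, 0 were called by either adjustment or by those other tools, with 3 at an unadjusted p under 0.05. Their median log2 fold change was 0.09. The highest of them were Snhg1, with a log2 fold change of 0.35, standard error 0.133 and adjusted p 0.176, and Snhg5, with 0.30, standard error 0.114 and adjusted p 0.169. The camera adjusted p was 0.840 for the neighbours and 0.404 for the host genes.

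Across the transcriptome, 260 genes were higher and 695 lower in the Gas5 libraries, of 17563 tested with edgeR. The lower genes made up 72.8% of the calls. The changes reached 1 on the log2 scale for 61 higher and 163 lower genes. In all 955 called genes the groups did not overlap, as was the case for 27.7% of all tested genes, against 10% by chance. Placeholder symbols accounted for 37 of the higher and 71 of the lower genes. The calls numbered 4 higher and 111 lower without GFP B, 6 and 101 without GFP C, and 112 and 500 without Gas5 A. With the cortical marker score as a covariate the quasi-likelihood test of edgeR called 0 genes in either direction, with 395 at an unadjusted p under 0.05, against 260 and 695 calls without it, and 33 of the 81 named genes other than Gas5 changed sign. With the same covariate limma-voom called 0 and 0 and DESeq2 0 higher and 1 lower. In simulated counts without an effect of the score, the edgeR fit recovered 13% of genes changed by 1 on the log2 scale.

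**Figure D2:**
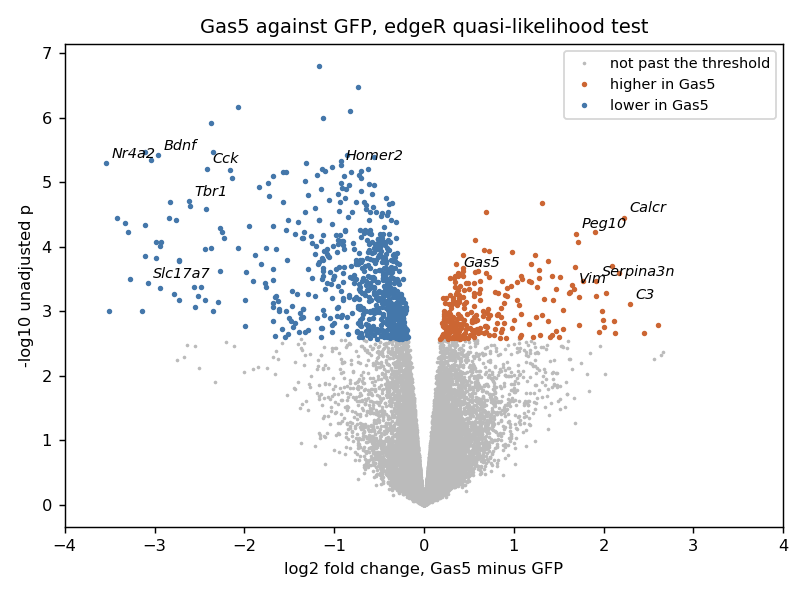
Log2 fold change, Gas5 minus GFP, on the horizontal axis against minus log10 of the unadjusted edgeR p on the vertical axis for 17563 genes. The 260 genes higher in the Gas5 libraries are orange, the 695 lower genes blue and the others grey, and Gas5 sits at 0.38.

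Genes that mark glutamatergic projection neurons of the cortex, among them Slc17a7, Neurod2 and Nrn1, were among the named genes with the largest decreases. Slc17a7, the vesicular glutamate transporter of cortical neurons, fell from 206 CPM ± 47.9 to 24.5 CPM ± 18.4 (SD, n = 3 each), 8.43-fold lower in the Gas5 group with an adjusted p of 0.0189. The transcription factor genes Neurod2 and Tbr1 were lower by 7.16-fold and 6.14-fold, with adjusted p of 0.00809 and 0.00642. Nrn1, which encodes a neuritin, was 7.12-fold lower. Of 11 tested members of the fixed list of cortical excitatory neuron markers, 8 fell and 0 rose over all genes, and 9 fell adjusted over the list alone. The median log2 fold change was -2.62, with a camera adjusted p of 1.1e-17 and an adjusted p of 0.413 with an estimated correlation. Without GFP B or without GFP C 4 members were called, lower. Cux2 and Lamp5, also on the list, had log2 fold changes of -0.01 and 0.10 and were not called. The mean log2 CPM of the list was 1.997, 2.67 and 2.86 in Gas5 A, B and C and 3.85, 4.34 and 4.39 in GFP A, B and C. This score is referred to as the cortical marker score.

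The other genes with the largest decreases were Nr4a2, an orphan nuclear receptor, at 11.6-fold lower, and Igfn1 at 10.7-fold lower. Slc30a3, the zinc transporter of synaptic vesicles, was 8.61-fold lower, Rtn4rl2, a Nogo receptor family member, 8.58-fold, and Bdnf, a neurotrophin, 7.81-fold. Ctgf, which encodes a connective tissue growth factor, was 7.66-fold lower, but 51.4% of its span is shared with other genes and not counted. Adjusted p for these 6 genes lay between 0.00473 and 0.0111. The cortical marker score was 2.51 in the Gas5 group and 4.19 in the GFP group beside them. With it as a covariate edgeR called 0 genes in either direction, and Ctgf alone of these 6 changed sign. Their decreases therefore cannot be told apart from the difference in the score. Slc30a3 and Nrn1 share 19.3% and 29.9% of their spans.

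Of 27 tested immediate-early genes, which neurons transcribe soon after activity, 6 fell and 0 rose over all genes, and 15 fell adjusted over the list alone. The median log2 fold change of the list was -0.37, with a camera adjusted p of 8.4e-13, an adjusted p of 0.413 with an estimated correlation and a fry adjusted p of 0.0888. The count over all genes was 12 with DESeq2 and with the exact test, 13 without the expression filter, 4 with robust dispersion and without Gas5 A, and 2 without GFP B and without GFP C. Nr4a2 and Bdnf had the largest decreases, at -3.54 and -2.96 on the log2 scale, ahead of Nr4a1 at -0.75, Arc at -0.69, Egr1 at -0.67 and Homer1 at -0.35. Fos had a log2 fold change of -0.39 with an adjusted p of 0.457 and was not called. The cortical marker score was lower in the same libraries, at 2.51 ± 0.454 against 4.19 ± 0.298 (SD, n = 3 each).

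Glutamate receptors and postsynaptic scaffolds had 5 of 26 tested members lower and 0 higher, or 6 lower adjusted over the list alone. Homer2, a postsynaptic scaffold, was 1.90-fold lower with an adjusted p of 0.00473, and Shank1, another scaffold, was 1.31-fold lower with an adjusted p of 0.010. The list had a median log2 fold change of -0.13, a camera adjusted p of 2.1e-05 and an adjusted p of 0.432 with an estimated correlation. Without Gas5 A the median was -0.07. Over all genes 3 members were called, lower, under upper quartile scaling, without Gas5 A and without GFP A, 1 without GFP B and 2 without GFP C, and with the cortical marker score as a covariate the camera adjusted p was 0.145. Among opioid and neuropeptide genes 4 of 26 fell and 0 rose, with 5 lower and 1 higher adjusted over the list alone. Over all genes 2 were higher and 5 lower with DESeq2, 3 and 5 without the expression filter, 1 and 2 without Gas5 A, 2 and 3 without GFP A, and 0 and 1 without Gas5 C, GFP B or GFP C. Cck, which encodes cholecystokinin, was 5.35-fold lower with an adjusted p of 0.00473, and Crhbp, a binding protein for corticotropin-releasing hormone, was 2.15-fold lower with an adjusted p of 0.0213. That list had a camera adjusted p of 0.289, and its median of -0.02 became 0.00 under upper quartile scaling. The cortical marker score was 2.51 in the Gas5 group and 4.19 in the GFP group alongside both lists.

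Of 12 tested reactive astrocyte genes 4 rose and 0 fell over all genes, and 7 rose adjusted over the list alone. The median log2 fold change of the list was 0.67, with a camera adjusted p of 1.4e-08 and an adjusted p of 0.413 with an estimated correlation. Over all genes 7 of 13 were higher without the expression filter, 1 with robust dispersion, 1 without GFP C and 0 without GFP B. Serpina3n, a serine protease inhibitor gene induced in reactive astrocytes, rose from 7.97 CPM ± 3.35 to 30.8 CPM ± 12.1 (SD, n = 3 each), 3.77-fold with an adjusted p of 0.0184. C3, a complement component, rose 4.92-fold, Lcn2, which encodes lipocalin, 3.75-fold, and Vim, which encodes the filament protein vimentin, 3.18-fold, with adjusted p of 0.0273, 0.010 and 0.0210. Without Gas5 A the median of the list was 0.36, and with the cortical marker score as a covariate it was -0.36 with a camera adjusted p of 0.245. The general astrocyte markers had 1 of 14 members higher, and 2 adjusted over the list alone. The 1 was Aqp4, a water channel gene, at 1.30-fold with an adjusted p of 0.0486, and it shares 36.7% of its span with other genes. The camera adjusted p of the general astrocyte markers was 0.0286, and 0.625 with an estimated correlation. That call was lost without Gas5 A (adjusted p 0.0856), Gas5 C (0.126) or GFP C (0.135). With the cortical marker score as a covariate the list turned lower, with a camera adjusted p of 0.0068, and 0.776 with an estimated correlation. Over all genes 3 astrocyte markers were higher without the expression filter, 2 with DESeq2, with the exact test and without Gas5 B, and 0 with limma-voom, with robust dispersion and without Gas5 A, Gas5 C, GFP B or GFP C. The cortical marker score was lowest, at 1.997, in Gas5 A, the library with the highest Serpina3n and Vim.

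Proliferation genes had 3 of 17 tested members higher and 0 lower, or 12 higher adjusted over the list alone. Over all genes 7 were higher with DESeq2, 8 with the exact test and without the expression filter, 1 with limma-voom and without Gas5 A, and 0 without GFP A, GFP B or GFP C. Rrm2, a subunit of ribonucleotide reductase, rose 3.87-fold with an adjusted p of 0.0438, and Mki67, a marker of cycling cells, 1.51-fold with an adjusted p of 0.0357. The median log2 fold change was 1.0, with a camera adjusted p of 5.6e-08 and an adjusted p of 0.432 with an estimated correlation. The median was 0.60 without Gas5 A and 0.43 over the 11 members that passed the filter of 1 CPM in 3 libraries. With the cortical marker score, at 2.51 against 4.19 in these libraries, as a covariate the camera adjusted p was 0.937 and the median -0.11. All 35 tested interferon response genes had a positive log2 fold change, with a median of 0.47, a camera adjusted p of 2.2e-08 and an adjusted p of 0.612 with an estimated correlation. The median was 0.30 without Gas5 A and 0.24 without GFP B. The mean log2 CPM of the list was 5.34, 4.76 and 4.88 in Gas5 A, B and C. It was 4.76, 3.90 and 4.76 in GFP A, B and C, so Gas5 B lay level with GFP A and GFP C. The estimated correlation between the 35 genes was 0.876, so they are far from independent. With edgeR 1 of them was called, and 0 adjusted over the list alone, against 3 with DESeq2, 5 with the exact test and 8 without the expression filter, and 0 with the filter of 1 CPM, with robust dispersion and without Gas5 A, Gas5 B, Gas5 C, GFP B or GFP C. The gene called, H2-D1, a class I histocompatibility gene, rose 1.79-fold with an adjusted p of 0.0490, and its paralog H2-K1, with a log2 fold change of 0.94, had an adjusted p of 0.0555. Reads of such paralogs could be split between them. With the cortical marker score as a covariate, H2-D1 had a log2 fold change of -0.40 and the interferon list turned downward, with a camera adjusted p of 5.1e-06 and an adjusted p of 0.776 with an estimated correlation.

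The other genes with the largest increases were Calcr, the calcitonin receptor gene, at 4.68-fold, Peg10, a paternally expressed gene of retrotransposon origin, at 3.23-fold, Igsf1 at 3.22-fold, A2m, an alpha-2-macroglobulin gene, at 3.14-fold, Glt8d2 at 2.92-fold, Sycp2l at 2.86-fold and Iqgap3 at 2.71-fold. Peg10 was the most abundant of them, at 163 CPM ± 42.7 against 50.3 CPM ± 14.4 (SD, n = 3 each). Adjusted p for these 7 genes lay between 0.00809 and 0.0419. Beside them the cortical marker score was 2.51 in the Gas5 group and 4.19 in the GFP group. With it as a covariate edgeR called 0 genes in either direction, and of these 7 Glt8d2 and Iqgap3 changed sign. The 7 increases therefore cannot be told apart from the difference in the score. Over all tested genes, edgeR called 4 higher without GFP B and 6 without GFP C.

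Microglia markers had positive log2 fold changes in all 14 tested members, with a median of 0.32. With edgeR 0 were called over all genes, with 11 at an unadjusted p under 0.05, and 10 were higher adjusted over the list alone, among them C1qa with a log2 fold change of 0.35 and an adjusted p of 0.0502 over all genes. Over all genes, 4 were called under upper quartile scaling, 8 without the expression filter, 3 with robust dispersion, 6 with DESeq2, 1 with limma-voom, 8 with the exact test, and 1 with the filter of 1 CPM, without Gas5 B and without Gas5 C. The camera adjusted p was 1.0e-06, and 0.413 with an estimated correlation. Oligodendrocyte markers went the other way, with negative log2 fold changes in all 15 members and a median of -0.22. Aspa, an aspartoacylase gene, was the 1 member called, 1.28-fold lower with an adjusted p of 0.0467, and 5 were lower adjusted over the list alone. Over all genes 4 were lower without the expression filter, 3 with DESeq2, 2 with the exact test and without Gas5 C, and 0 under upper quartile scaling, with limma-voom and without Gas5 A, Gas5 B, GFP B or GFP C. That list had a camera adjusted p of 4.0e-05, and 0.413 with an estimated correlation. Ependymal markers had 1 of 5 higher, Rsph1, a cilium gene, at 1.82-fold with an adjusted p of 0.0293, and 3 adjusted over the list alone, with a camera adjusted p of 0.00471 and 0.413 with an estimated correlation. Over all genes 2 ependymal markers were higher with DESeq2 and 3 with the exact test, and 0 without Gas5 A, Gas5 B, GFP B or GFP C. The cortical marker score was 2.51 in the Gas5 group and 4.19 in the GFP group beside these 3 lists, and with it as a covariate the camera calls were lost, with adjusted p of 0.850 for microglia, 0.766 for oligodendrocytes and 0.766 for ependymal cells.

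Markers of the principal neurons of the accumbens, the medium spiny neurons, were not called as a group in the main test. With edgeR 0 of 16 tested general markers passed the threshold by either adjustment, with 4 at an unadjusted p under 0.05, while DESeq2 and the exact test each called 1, lower, and limma-voom 0, and their median log2 fold change was -0.0047 (0.019 under upper quartile scaling), with a camera adjusted p of 0.840. Drd1 and Drd2, the dopamine receptor genes of the main neuron types, had log2 fold changes of 0.03 and 0.05. Isl1, a transcription factor gene, rose 1.64-fold with an adjusted p of 0.0345 among 10 Drd1 neuron markers, and Grik3, a kainate receptor gene, was 1.18-fold lower with an adjusted p of 0.0355 among 7 Drd2 neuron markers. These lists had camera adjusted p of 0.661 and 0.944. Adjusted over the list alone, 2 were higher and 1 lower for Drd1 neurons, and 1 higher and 2 lower for Drd2 neurons. Of 26 dopamine and cAMP signalling genes, Ddc rose 1.90-fold and Adcy1 was 1.72-fold lower, with adjusted p of 0.0236 and 0.0175. Ddc encodes dopa decarboxylase and shares 20.5% of its span with other genes, and Adcy1 encodes an adenylyl cyclase. Adjusted over the list alone, 3 were higher and 1 lower, and the camera adjusted p was 0.637, or 0.0481 without Gas5 A. With the cortical marker score as a covariate camera called this list and the general medium spiny neuron list higher (adjusted p 1.5e-05 and 5.4e-06). With an estimated correlation the adjusted p of each was 0.776. Gabbr2 and Gabrg1, receptor genes for GABA, had log2 fold changes of -0.49 and 0.83 and adjusted p of 0.0115 and 0.0224, among 2 higher and 2 lower of 17 GABA genes (3 and 3 adjusted over the list alone), with a camera adjusted p of 0.944. With edgeR without GFP B or without GFP C, 0 members of the Drd1, Drd2, dopamine and GABA lists were called over all genes, and with DESeq2 the higher and lower counts were 2 and 2, 0 and 2, 3 and 1, and 3 and 2.

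**Figure D3:**
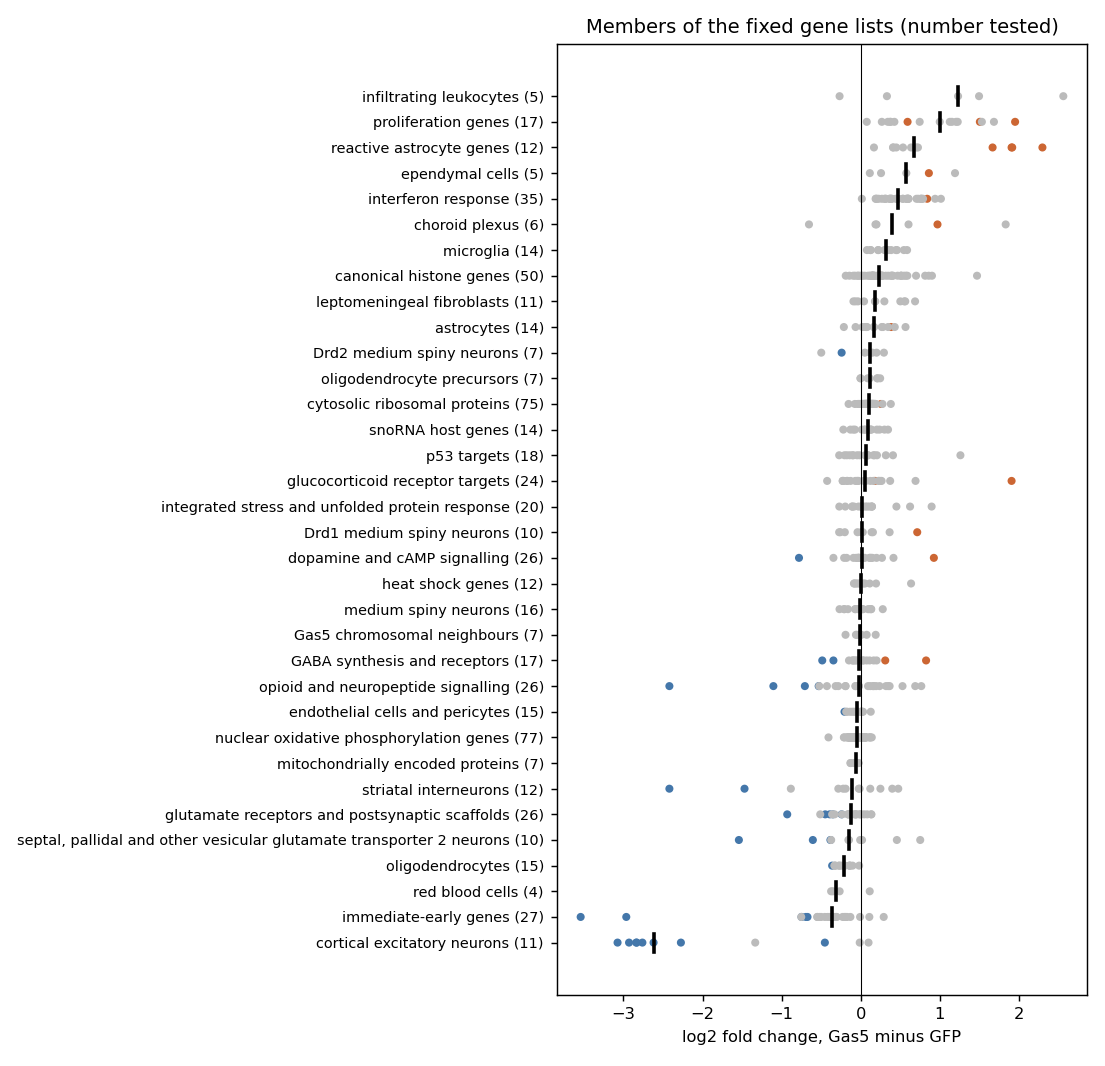
Log2 fold change, Gas5 minus GFP, of each tested member of the 34 gene lists, with the list median as a black bar. Members past the adjusted threshold are orange where higher and blue where lower in the Gas5 libraries. The cortical excitatory neuron markers have the lowest median, at -2.62.

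Among other neurons, the interneuron list had 2 of 12 members lower, Cck and Vip, or 3 adjusted over the list alone. Vip, a peptide gene, was 2.77-fold lower with an adjusted p of 0.0218. The mean log2 fold change of the list was -0.36 and the median -0.11, with Cck at -2.42 and Vip at -1.47 drawing the mean down. The list had 4 members with a positive and 8 with a negative value. Its camera adjusted p was 0.0286, and 0.413 with an estimated correlation, and the call was lost on ranks (adjusted p 0.307), without Gas5 A (0.0633) and without GFP A (0.166), and 1 member was lower over all genes without GFP B or without GFP C. The septal, pallidal and vesicular glutamate transporter list had 3 of 10 members lower, among them Slc17a6, a vesicular glutamate transporter gene, at 2.91-fold with an adjusted p of 0.00473 and Ndnf at 1.52-fold with an adjusted p of 0.0424. Adjusted over the list alone, 4 were lower and 1 higher, with a camera adjusted p of 0.0179, and 0.413 with an estimated correlation. That call was lost on ranks (adjusted p 0.146) and without Gas5 B (0.103), and the median of -0.15 was -0.23 without Gas5 A, -0.24 without GFP B and -0.07 without Gas5 C or GFP C. Over all genes 1 member was lower without GFP A, GFP B or GFP C. The cortical marker score was 2.51 in the Gas5 group and 4.19 in the GFP group beside both lists.

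Glucocorticoid receptor targets, of interest because Gas5 can bind that receptor, had 2 of 24 members higher and 0 lower by either adjustment. These were Lcn2, which is also on the reactive astrocyte list, and Mertk, a phagocytic receptor gene, at 1.13-fold with an adjusted p of 0.0491. Over all genes 1 was higher with limma-voom, with RLE size factors and without any 1 library other than GFP B, and 0 without GFP B. At an unadjusted edgeR p under 0.05 there were 6 members, 4 higher and 2 lower. The list, which also holds the receptor genes Nr3c1 and Nr3c2, had a camera adjusted p of 0.462.

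Of the lists of general cell functions, ribosomal proteins had 1 of 75 members higher, Rpl18 at 1.19-fold with an adjusted p of 0.0454, and 0 adjusted over the list alone. Their median log2 fold change was 0.10, with a camera adjusted p of 1.3e-04 and 0.643 with an estimated correlation. Rpl18 shares 47.3% of its span with other genes. Without Gas5 A the median was 0.05, and without any 1 library 0 members were called by edgeR over all genes. Histone genes had 1 of 50 higher, Hist1h2be at 1.19-fold with an adjusted p of 0.0400, and 0 adjusted over the list alone, with a median of 0.23, a camera adjusted p of 3.3e-04 and 0.612 with an estimated correlation, and a median of 0.13 without Gas5 A. Over all genes 3 histone genes were higher with the exact test, 2 without GFP A, and 0 without any other 1 library. Nuclear oxidative phosphorylation genes had 0 of 77 called by edgeR with either adjustment and 0 by DESeq2, limma-voom or the exact test, with 11 at an unadjusted p under 0.05. Their median was -0.05 (-0.03 under upper quartile scaling), with a camera adjusted p of 0.0413 and 0.612 with an estimated correlation. That call was lost with the filter of 1 CPM (adjusted p 0.0679) and without Gas5 A (0.0856), Gas5 B (0.102) or GFP A (0.264). It was also lost with the cortical marker score as a covariate (0.166). Camera placed 8 lists higher and 7 lower in all at the preset correlation. With an estimated correlation, or by fry, 0 lists passed, with 3 and 12 at an unadjusted p under 0.05. The 3 were cortical excitatory neurons (camera unadjusted p 0.0181), ependymal cells (0.0319) and immediate-early genes (0.0496). The adjustment gave these and other lists, up to interneurons at an unadjusted p of 0.109, the same adjusted p of 0.413. With the cortical marker score as a covariate 9 lists passed, of which 6 had the opposite direction, and 0 passed with an estimated correlation. Ribosomal proteins and histone genes were among the 6, both turning lower (camera adjusted p 2.0e-04 and 3.6e-04). Heat shock genes and medium spiny neurons, also among them, had no call without the covariate (camera adjusted p 0.586 and 0.840).

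The remaining lists did not pass camera. Its adjusted p was 0.661 for p53 targets, where Zmat3 had a log2 fold change of -0.27 and an adjusted p of 0.050, just over the threshold, 0.586 for heat shock genes, 0.495 for the integrated stress and unfolded protein response, and 0.315 for mitochondrially encoded proteins. It was 0.131 for oligodendrocyte precursors, 0.117 for leptomeningeal fibroblasts, 0.130 for infiltrating leukocytes, 0.462 for red blood cells, 0.0749 for choroid plexus and 0.297 for endothelial cells and pericytes. Some of these calls appeared when 1 library was left out. Infiltrating leukocytes had an adjusted p of 0.00473 without Gas5 B and 0.00707 without GFP C, leptomeningeal fibroblasts 0.0194 and 0.0218 without the same libraries, choroid plexus 0.0451 without Gas5 A and 0.0207 without Gas5 B, and mitochondrially encoded proteins 0.0443 without GFP C. Over all genes, Kl, which encodes klotho, was 1.96-fold higher with an adjusted p of 0.0200 on the choroid plexus list, and Flt1, a receptor gene for vascular growth factor, was 1.15-fold lower with an adjusted p of 0.0300 on the endothelial list. The choroid plexus count was 0 without GFP B or GFP C, and the endothelial count 0 without any 1 library other than Gas5 C. Adjusted over the list alone, the counts of higher and lower members were 1 and 1 for p53 targets, 2 and 0 for oligodendrocyte precursors, 3 and 0 for leptomeningeal fibroblasts, 1 and 0 for infiltrating leukocytes, 1 and 0 for choroid plexus, 0 and 1 for endothelial cells, and 0 and 0 for the others of these lists.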

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

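The covariate, span and overlap alternatives were chosen after seeing the data, and the others before the data were examined. All 260 higher and 695 lower genes kept their direction under the scaling, filter, tool, dispersion and block alternatives in which they were tested. Without the expression filter 656 genes were higher, with DESeq2 494, and with the exact test of edgeR 681 were higher and 1093 lower. On simulated data the latter tools made more false calls, 13.6% and 18.1%. At an adjusted p under 0.1 the counts were 661 and 1086, and at a log2 fold change of at least 1 they were 61 and 163, by construction. When genes sharing any span were left out, 119 and 287 of the 8594 genes left were called, fewer because fewer genes were tested. Leaving out 1 library at a time gave between 4 and 251 higher genes, between 101 and 611 lower genes, between 13 and 17 lists past camera, and a Gas5 log2 fold change between 0.33 and 0.42. The low counts, 4 and 111 without GFP B and 6 and 101 without GFP C, come with fewer samples, yet without GFP A they were 236 and 611, and the cause was not tested. Higher genes numbered 112 without Gas5 A. The Gas5 adjusted p ranged from 1.5e-04 to 1.0 over all alternatives. Camera with an estimated correlation passed 0 lists, with 3 at an unadjusted p under 0.05, and fry 0, with 12. Over all alternatives the values of the other 81 named genes kept direction and side of the threshold 1188 times, lost the call 170 times, gained it 90 times and reversed 33 times.

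The labels do not say that the replicate letters pair the samples, and the data do not show it for every letter, so they were not treated as pairs. With the replicate letter as a block 510 genes were higher and 928 lower, Gas5 had a log2 fold change of 0.38 with an adjusted p of 0.0159, and 14 lists passed camera. On simulated data 12.5% of the calls of this fit were false, against 6.99% without the block, and it recovered 62% of genes changed by 0.5 on the log2 scale, against 65%. The simulated counts held no effect of the letter, so these values cannot show whether the letters pair the samples. The block ended the calls of the septal and pallidal list (adjusted p 0.136) and of nuclear oxidative phosphorylation (0.144) and gave infiltrating leukocytes one (0.0305). It called 15 of 35 interferon response genes, against 1 without it, and 6 of 14 microglia markers, against 0. Deviations from the group means of libraries with the same letter correlated across genes at 0.16 for A, 0.18 for B and -0.09 for C, with the A libraries and the B libraries each correlating best with each other, Gas5 C with GFP A and GFP C with Gas5 B.

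With the cortical marker score as a covariate 0 genes were higher and 0 lower, with 395 at an unadjusted p under 0.05, and 9 lists passed. With an estimated correlation 0 lists passed, with 2 at an unadjusted p under 0.05. The same covariate in DESeq2 gave 0 higher genes and 1 lower, with 197 at an unadjusted p under 0.05, and in limma-voom 0 and 0, with 439. Gas5 was at 0.38 (adjusted p 1.0) in edgeR, with standard errors of 0.187 in edgeR, 0.270 in DESeq2 (log2 fold change 0.39) and 0.181 in limma-voom. This score nearly coincides with the groups. In simulation the fit recovered 13% of genes changed by 1 on the log2 scale, and 9 of its 22 calls there were false (40.9%). The simulated counts held no effect of the score, so these values cannot show how far the lost calls reflect low power. Of the main calls 189 of 260 and 522 of 695 kept direction. All reversals were under this covariate, and the cause was not tested for any of them. The log2 fold changes were 0.62 for Slc17a7, 0.31 for Ctgf, 0.18 for Adcy1, 0.0369 for mt-Co1, 0.0106 for Cox6a1, 0.24 for Plxdc1, 0.0198 for Arpp21, 0.0038 for Dach1, 0.15 for Mbp and 0.0201 for Slco1a4. They were -0.235 for Serpina3n, -0.0525 for Vim, -0.50 for Glt8d2, -0.10 for Iqgap3, -0.40 for H2-D1, -0.22 for H2-K1, -0.0195 for Mki67, -0.11 for Rrm2, -0.41 for Hspb1, -0.0603 for Hspe1, -0.27 for Atf3, -0.29 for Gabrg1, -0.13 for Ddc, -0.13 for Rps12 and -0.28 for Hist1h1d. They were -0.11 for Isl1, -0.16 for Aqp4, -0.37 for Aldh1l1, -0.0140 for Cd68, -0.33 for Rarres2, -2.14 for Prlr, -1.25 for Ly6c2 and -0.60 for Ms4a4b. Of the 9 lists past the threshold at the preset correlation, 2 had the direction of the main test, immediate-early genes lower (adjusted p 2.5e-04, and 0.776 with an estimated correlation) and the septal and pallidal list lower (2.3e-05, and 0.304), and dopamine and cAMP signalling gained a call, higher (1.5e-05, and 0.776). Without the covariate the first 2 also lost their calls with an estimated correlation (adjusted p 0.413 each). The lists that turned had, at the preset correlation, adjusted p of 5.1e-06 for interferon response, 0.00263 for heat shock genes, 2.0e-04 for ribosomal proteins, 3.6e-04 for histone genes, 5.4e-06 for medium spiny neurons and 0.00682 for astrocytes, and with an estimated correlation 0.304 for histone genes and 0.776 for the others. Of these, heat shock genes and medium spiny neurons had no call without the covariate (camera adjusted p 0.586 and 0.840), so they gained one. The reactive astrocyte, proliferation, glutamate receptor, oxidative phosphorylation, interneuron, oligodendrocyte, microglia and ependymal lists lost their calls. The cortical list lost its call too, but the score is the mean of that list, so this loss was fixed in advance and is no evidence. Slc17a7, which changed sign, is itself 1 of the genes in the score.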

Other observations

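The tests of cortical tissue in the lower genes, of library Gas5 A, of the neuron share and of the other snoRNA host genes were chosen only after the results were seen. Beyond the fixed rule, the cortical marker list itself was uneven. Emx1 and Neurod6, chosen here after their values were seen, had log2 fold changes of -2.27 and -2.76, Rorb -0.45, and Cux2 -0.01 at 91.2 CPM in the Gas5 group and 92.0 CPM in the GFP group. Among immediate-early genes, Nr4a2 and Bdnf were the 2 members with decreases beyond 1 on the log2 scale. Lower genes spanned a median of 64.7 kb and higher genes 42.6 kb, against 24.0 kb for all tested genes.

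Of the 10 splits of the 6 libraries into 3 and 3, only the real 1 gave as many calls, 955, and the highest of the other splits gave 0. Splits this few cannot give a share under 0.05. The other splits had between 169 and 1619 genes at an unadjusted p under 0.05, against 3766 for the real grouping.

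The 695 lower genes include most cortical excitatory markers, and a candidate explanation is that the GFP samples held more cortical tissue. In the 687 lower genes outside the marker list, the median slope on the cortical marker score within groups was 0.618 of that between groups (95% bootstrap interval over genes 0.552 to 0.671, and genes are not independent), and 88.4% were lower in GFP A, the GFP library with the lowest score, than in the other GFP libraries, against 48.3% of uncalled genes. Gene length is argued against as the whole cause, since the median log2 fold change of the lower genes was -0.515 after the trend with span was removed and -0.534 before. The slope cannot separate dissection from any other process that varies within groups along the same axis, and the flat values of Cux2 and Lamp5 show no gain of those markers, though a high level in the accumbens itself could hide one. An effect of Gas5 on these genes stays open and untested.

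Over all genes 4 of 12 reactive astrocyte and 3 of 17 proliferation genes were higher in the Gas5 libraries, and with an estimated correlation the lists had adjusted p of 0.413 and 0.432. Gas5 A alone is argued against, since the median log2 fold change of the 29 genes of both lists was 0.451 without it and 0.724 with it. A lower share of neurons as the only change would raise all glial markers alike. Microglia markers instead exceeded oligodendrocyte markers by a mean of 0.540 (standard error over genes 0.0487). Genes are not independent, with estimated correlations of 0.40 within the microglia list and 0.19 within the oligodendrocyte list. The values cannot weigh a lower share of neurons that came together with another difference in tissue. Among the 260 higher genes 85.8% were higher in GFP A than in the other GFP libraries, against 51.7% of uncalled genes, so these genes also vary within groups with the cortical marker score. A difference in injury or placement of the injection, and a response to Gas5, stay open and untested.

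Gas5 itself was 1.30-fold higher, and less cortical tissue in the Gas5 samples could contribute. With the cortical marker score in the model its log2 fold change was 0.379 with a standard error of 0.187 (unadjusted p 0.0778), against 0.380 and 0.0633 without it. The call ended because the standard error grew, and the value passed 2 standard errors narrowly here but not in DESeq2 (0.388, standard error 0.270), so a difference in tissue and an effect of the vector cannot be told apart in a fit of this power. A rise shared by all other snoRNA host genes is argued against, since their median log2 fold change was 0.0870 (SD over 14 genes 0.167, 4 of them negative). Gas5 exceeded Snhg1, the highest of them, by 0.0341 with a standard error of 0.147, so a rise shared with single hosts stays open.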
